A study of Rattus norvegicus with 9 samples.

How the data were processed

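MBD3 ChIP-seq peak lists of 7 rats were used, 3 sham-operated and 4 stimulated, with groups taken from the treatment label of each sample. Each list belongs to a separate animal, per the rat numbers in the labels. Per the labels' protocols, the stimulated animals received 400 µA pulses for 20 min and diazepam at 20 mg/kg to end status epilepticus, and all were killed on day 14. Per the labels' protocols, 25 µg of crosslinked chromatin was precipitated with 4 µg of an anti-MBD3 antibody. The 2 input samples are labelled 1 per group and entered only through the authors' peak calling.

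The submitters' processing notes name cutadapt 1.7.1, Bowtie 1.0.0 and MACS2 2.1.0.20141030. Peaks were called per rat and not on pooled samples, per the file headers, with the group's input library as control. Per the file headers, MACS2 extended 50 bp tags to 150 bp without building a model, kept 1 tag per position, reported sub-summits and used a q threshold of 0.1. The effective genome size was the mouse preset of 1.87 Gb, per the file headers, while the last peak ends of the chromosomes in the lists sum to 2.90 Gb. The genome build is not given in the sources used here.

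The deposited lists give each peak's pileup, a signal in tags at the summit. They also give the −log10 p-value and −log10 q-value that the authors' peak caller assigned. The deposited fold enrichment is a ratio of pileup to local background, each raised by 1. These values belong to a peak within its own list, so they served to describe, rank or filter peaks within that list.

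Depth was taken from the tag totals in the file headers. Filtered ChIP tags ranged from 2436208 to 17960510 per library. Depth and input library differ between groups in the same way as the treatment, so their effects cannot be separated from it. Diazepam is recorded for the stimulated rats alone, so its effect cannot be separated from that of stimulation. Intervals of shares of peaks are 95% Clopper-Pearson intervals. The 95% counting intervals of gene density came from Poisson redraws of each list's peak counts per chromosome. Both kinds cover counting error only.

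Entries were used as deposited for peak number, for medians and shares of fold enrichment and −log10 q in whole lists, and for chromosome shares and gene density of whole lists. Entries with the same start and end were counted once for covered length, widths, overlaps, regions, 1 Mb windows and equal lists. Coordinates are those of the deposited lists, counted from 1. Peak number and covered length were compared on the log10 scale with exact two-sided permutation tests over all 35 splits of the 7 rats, with p as 2 times the smaller tail. Lists were compared by the number of peaks sharing at least 1 bp, divided by the number expected if lists of these sizes and widths were placed at random on each chromosome, with 0.5 added to both. The log2 ratio was averaged over both directions, and the difference within minus between groups was tested exactly, one-sided, over the 35 splits. Peak counts in 1 Mb windows with a peak in any list were compared by Spearman's rho for each pair of lists, and the mean within minus between groups was tested in the same way. Peaks of all lists that overlapped were merged into regions, and each region was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Chance counts of regions came from 100 independent circular shifts of every list along each chromosome.

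The named regions were fixed by rule: up to 10 regions called in all stimulated and no sham rats, up to 10 called in all sham and no stimulated rats, and up to 10 called in all rats. Each set was ranked by the lowest fold enrichment among the rats with the peak, highest first. This rule, the groups, the tests and the first group of other settings below were set before the data were examined. The chromosome shares, the window correlations with all their settings, the counts for stimulated rats 2 and 4, and the settings listed last were chosen afterwards.

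The gene table at hand is of assembly GRCr8. Peaks extend past the last gene of that table on 13 of 21 chromosomes, so the lists use another build and no peak was assigned to a gene. The share of peaks at promoters, the CpG content of peaks, the 16 gene lists fixed beforehand and the genes with peaks in 1 group were not analysed here for that reason. Only the number of protein-coding genes per Mb of each GRCr8 chromosome was used, in the closing observations.

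The other settings fixed in advance were the stronger peaks of each list (at or above its median −log10 p), a −log10 q of at least 3, at least 4-fold enrichment, autosomes and X alone, lists cut to the same number of strongest peaks, a stricter overlap, merging across gaps of up to 500 bp, raw means, and leaving out each rat. Settings added after seeing the data were distinct intervals, peaks relative to filtered tags, chance from circular shifts, p-values from absolute differences, removal of each chromosome's mean rank from window counts, splits of the rats on equal lists, peaks wider than 1 kb left out, and stimulated rats 1 and 3 left out together. The code was tested on simulated lists with 23734 regions. It recovered 200 of 200 planted regions of all rats, 60 of 60 planted in stimulated rats alone and 39 of 40 planted in sham rats alone. The simulated lists covered chromosome 1 alone. Planted peaks began at the same position in every list, so offsets between peaks were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.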

Results

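MBD3, a subunit of the NuRD chromatin remodelling complex with a methyl-CpG-binding domain, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in male Sprague-Dawley rats. The tissue held the entorhinal, perirhinal and piriform cortices together with the amygdala. In 4 rats the lateral amygdala had been stimulated electrically for 20 min to evoke status epilepticus, a model of temporal lobe epilepsy, and 3 sham-operated rats carried electrodes without stimulation. Diazepam to end status epilepticus is recorded for the stimulated rats alone. Tissue was taken 14 days after stimulation. One list of MBD3 peaks per rat was analysed, and the series asks whether binding differed between stimulated and sham-operated animals.

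The libraries of the groups differed in depth. After removal of duplicates the sham libraries held 3668143, 2718183 and 2436208 ChIP tags, and the stimulated libraries 17960510, 7631096, 4812579 and 12357373, in the order of replicates 1 to 4. Every stimulated library was deeper than every sham library (exact permutation test, two-sided p = 0.0571, n = 3 and 4). Two-sided permutation p-values were taken as 2 times the smaller tail, for which 0.0571 is the smallest value over 35 splits of 7 rats, so these tests could not reach 0.05. Duplicates made up 78.3% of the tags of stimulated rat 3 and between 9.10% and 39.1% in the other 6 libraries. The input library used for the sham lists held 5241067 filtered tags and the one used for the stimulated lists 33279049.

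Stimulated rats had both the longest and the shortest lists of MBD3 peaks. Stimulated rat 2 had 109947 peaks and stimulated rat 4 had 65074, whereas stimulated rat 1 had 9500 and stimulated rat 3 had 2754. The sham rats lay between these values, with 32399, 14221 and 12269 peaks. The mean was 19630 ± 11102 peaks in sham rats (SD, n = 3) and 46819 ± 50507 in stimulated rats (SD, n = 4). The geometric mean of the stimulated rats was 1.17 times that of the sham rats, a difference well within the spread between rats (exact permutation test, two-sided p = 0.914, n = 3 and 4). Relative to filtered tags the ratio was 0.356, in the opposite direction (exact permutation test, two-sided p = 0.514, n = 3 and 4). The direction also turned when sham rat 3, stimulated rat 2 or stimulated rat 4 was left out, with log10 differences of −0.0137, −0.174 and −0.0978.

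**Figure D1:**
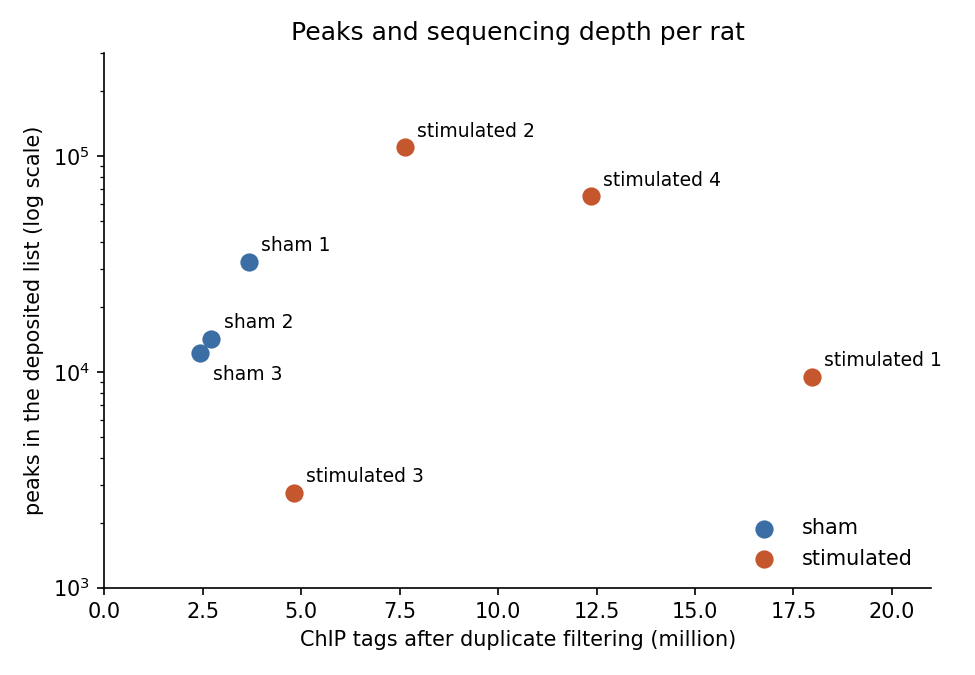
Number of MBD3 peaks in each rat's list (log scale) against its ChIP tags after duplicate filtering (2436208 to 17960510 tags); each point is 1 rat. The stimulated rats span 2754 to 109947 peaks, on both sides of the 3 sham rats, and all 4 lie to the right of the sham rats.

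The genome covered by MBD3 peaks followed the number of peaks. Peaks covered 5.99, 2.60 and 2.18 Mb in sham rats 1 to 3, and 1.76, 20.5, 0.466 and 12.3 Mb in stimulated rats 1 to 4. Mean peak width was 188, 187 and 180 bp in the sham lists and 189, 189, 173 and 192 bp in the stimulated lists. The geometric mean of covered length was 1.17 times as large in stimulated as in sham rats (exact permutation test, two-sided p = 0.914, n = 3 and 4), and its direction turned with the same 3 rats left out. The median of the authors' fold enrichment over background was 4.64, 4.93 and 5.02 in the sham lists and 4.07, 5.02, 4.58 and 4.73 in the stimulated lists. For 48.6% to 62.8% of the peaks of a list that background was about the genome-wide rate of ChIP tags. These medians therefore depend on library depth and are not enrichment over input alone. Peaks with a −log10 q of at least 3 made up 42.9%, 59.4% and 63.0% of the sham lists. The share was 75.2% in stimulated rat 2 and 66.5% in stimulated rat 4, but 17.9% in stimulated rat 1 and 19.1% in stimulated rat 3.

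The 3 sham rats shared MBD3 peaks far more often than random placement gives, and stimulated rats 2 and 4 shared peaks with them. Random placement takes no account of places prone to pileups in any library. Pairs of sham lists overlapped 55.6 to 68.8 times as often as randomly placed peaks of the same number and width. Stimulated rat 2 overlapped the sham lists 34.9-fold and stimulated rat 4 38.7-fold on average, against 9.43-fold for stimulated rat 3 and 1.15-fold for stimulated rat 1. With the 2696 strongest peaks of each list, these values were 94.2-, 47.2-, 10.9- and 2.42-fold for stimulated rats 2, 4, 3 and 1. Stimulated rat 2 then lay above the sham lists among themselves, at 38.7- to 70.4-fold. Among peaks of at least 4-fold enrichment the log2 ratio of stimulated rat 1 was −1.80. For stimulated rat 3 the log2 ratio was 3.24 over all peaks and 4.21 on autosomes and X alone. It was 2.44 at a −log10 q of at least 3. With the stricter overlap stimulated rats 2 and 4 had log2 ratios of 5.87 and 5.96, against 5.13 and 5.27. Of the peaks of sham rat 1, 48.1% met a peak of stimulated rat 2 and 32.2% a peak of stimulated rat 4, but 0.163% a peak of stimulated rat 1 (95% Clopper-Pearson interval 0.122 to 0.214%). Among the strongest 10% of sham peaks by p-value, 74.7% to 79.7% were also called in stimulated rat 2 and 61.5% to 66.3% in stimulated rat 4.

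Stimulated rat 1 shared few peaks with the other lists. Of its peaks, 111 met a peak of stimulated rat 2, fewer than the mean of 146.9 ± 12.5 (SD) over 100 circular shifts. This direction turned with equal lists, where the log2 ratio of observed to expected overlap was 2.22 against −0.44 for all peaks, and 4.61% of its strongest 10% met stimulated rat 2, against 1.19% of the whole list. A peak of stimulated rat 4 was met by 385 of them against a shifted mean of 91.9, and one of stimulated rat 3 by 46 against 9.90. Over all 21 pairs, an excess of shared peaks within groups was not beyond chance. The log2 ratio of observed to expected overlap averaged 5.98 in sham pairs, 2.44 in stimulated pairs and 3.46 between groups. Any excess within groups thus came from the sham pairs. The mean over all pairs within groups was higher by 0.16 (exact permutation test, one-sided p = 0.286, 3 sham and 4 stimulated rats). This difference was −0.61, −0.42 and −0.52 without sham rats 1, 2 and 3 in turn, and 0.23, 1.32, 0.55 and 0.90 without stimulated rats 1 to 4.

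**Figure D2:**
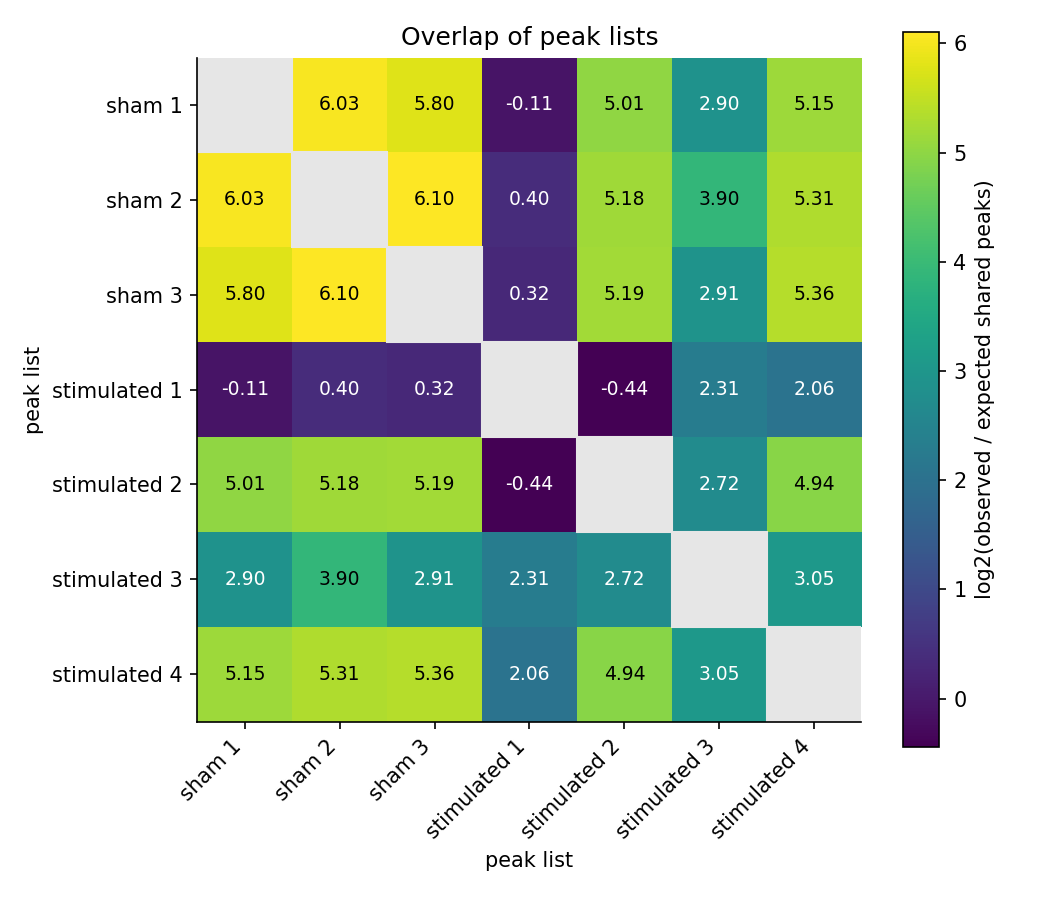
Log2 ratio of observed to expected shared peaks for each pair of the 7 lists, as the mean of both directions; rows and columns are rats and the colour gives the value printed in each cell. Pairs of sham rats lie at 5.80 to 6.10, whereas stimulated rat 1 lies between −0.44 and 2.31 with every other list.

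At the scale of 1 Mb windows, peak counts were on average more alike within groups than between them. Across 2786 windows, which are not independent replicates, Spearman's rho between lists was 0.41 to 0.53 within sham rats, 0.30 to 0.82 within stimulated rats and −0.01 to 0.49 between groups. Stimulated rat 1 had rho of 0.46, 0.30 and 0.62 with stimulated rats 2, 3 and 4, and of 0.01, −0.01 and 0.11 with sham rats 1 to 3. The mean was higher within groups by 0.25 (exact permutation test, one-sided p = 0.0286, the smallest possible value, 3 sham and 4 stimulated rats). With equal lists rho was 0.24 to 0.25 within sham rats, 0.14 to 0.43 within stimulated rats and −0.03 to 0.32 between groups. Sham rat 1 then had rho of 0.32 and 0.30 with stimulated rats 4 and 2, above every pair of sham rats. The difference of the means was 0.09 with equal lists (exact one-sided p = 0.0286) and 0.12 at a −log10 q of at least 3 (exact one-sided p = 0.0571). Without 1 rat it was 0.20 to 0.30, where the test could not reach 0.05. This comparison was added after the correlations were seen, and depth and input library differed between the groups in the same way.

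MBD3 regions seen in every sham rat were mostly present in 2 of the stimulated rats. The 7 lists merged into 176203 regions, of which 129893 (73.7%) came from 1 rat alone. A peak was present in 3 of 3 sham rats in 1584 regions. Of these, 1511 (95.4%) were also called in stimulated rat 2 and 1338 (84.5%) in stimulated rat 4, but 85 in stimulated rat 3 and 19 in stimulated rat 1. Stimulated rats 2 and 4 shared 29332 regions, and 18797 of them (64.1%) had no peak in any sham rat, whose libraries were all shallower.

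A peak in all 4 stimulated and no sham rat was found in 6 regions. They lay on chromosome 19 at 67047739 to 67048956, on chromosome 10 at 78004935 to 78005229, and at 4 places on chromosome 4 between 209834654 and 209839801. In the chromosome 19 region fold enrichment was 2.64, 3.63, 2.49 and 2.99 in stimulated rats 1 to 4, with pileups of 244, 100, 59 and 191 tags. Fold enrichment in the other 5 regions ranged from 1.54 to 3.46 and pileups from 11 to 196 tags. In regions seen in 1 rat the median pileup was 9, 7, 6 and 8 tags in stimulated rats 1 to 4. The median fold enrichment there was 4.10, 4.96, 4.88 and 4.52. Tall pileups at low fold were also seen in regions of all 7 rats, and high-copy sequence was not tested for these 6 regions. Independently shifted lists, in which all sharing between rats is broken, gave 0.01 such regions on average, and 9 of 35 splits of the rats gave at least 6. The count was 50, 18 and 35 without stimulated rats 1, 2 and 3 in turn, and 0 among peaks of at least 4-fold enrichment.

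The reverse pattern, a peak in all 3 sham and no stimulated rat, was found in 48 regions, and 10 of 35 splits of the rats gave as many. Shifted lists gave 0.11, a value that takes no account of the sharing among sham lists. The region ranked first lay on chromosome 14 at 92588852 to 92589024, with 6.18-, 6.57- and 5.86-fold enrichment in sham rats 1 to 3. The next were on chromosome 15 at 63274388 to 63274804, where the lowest value was 5.75-fold, and on chromosome 2 at 83741501 to 83741712, where it was 5.41-fold. All 10 regions ranked highest had pileups of 5 to 9 tags. With equal lists each of these 10 lost at least 1 sham rat, and the chromosome 14 region was called in 2. The count was 24 at a −log10 q of at least 3, 104 at 4-fold enrichment or more, 221, 555 and 733 without sham rats 1, 2 and 3, and 245 and 73 without stimulated rats 2 and 4.

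The regions could not be tested individually with 7 rats. Fisher's exact test (two-sided) gave 54 regions with an unadjusted p below 0.05, the smallest being 0.0286, and 0 after Benjamini-Hochberg adjustment over all merged regions (smallest adjusted p = 1). With a smallest possible p of 0.0286, the adjustment over 176203 regions could be passed only if most of them separated the groups completely, so the count of 0 was set by the design.

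A peak was called in all 7 rats in 13 regions. One was the whole mitochondrial chromosome, from 1 to 16313, which shifting cannot move and which was the 1 region shared by the shifted lists. The region ranked first was on chromosome 12 at 1488487 to 1488787, with fold enrichment between 2.33 and 3.59 and pileups between 28 and 150 tags. Other examples lay on chromosome 7 at 22488307 to 22488976, on chromosome 1 at 187765224 to 187766833 and on chromosome 20 at 42616741 to 42617353. Their fold enrichment ranged from 2.00 to 6.95, from 1.95 to 7.61 and from 1.80 to 8.49, with the lowest value in stimulated rat 1 each time. Without stimulated rat 1 the count was 85, and no shared region remained among peaks of at least 4-fold enrichment. The median local background of peaks in the 13 regions was at least 39.0 times the genome-wide one in every list. Whether these peaks reflect MBD3 binding or high-copy sequence stays open.

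Stimulated lists held larger shares of their peaks on chromosomes 8, 10, 12, 19 and 20 than any sham list, and smaller shares on chromosomes 2, 13, 16, 17, 18 and X. Chromosome 10 held 3.69% ± 0.221 of the peaks in sham rats (SD, n = 3) and 5.98% ± 1.16 in stimulated rats (SD, n = 4). Chromosome 12 held 1.84% ± 0.0487 and 2.95% ± 1.01, and the X chromosome 1.29% ± 0.0974 and 0.798% ± 0.179, for the same groups. Complete separation was seen on 11 of 21 chromosomes, where chance gives 5.71% of chromosomes, or 1.20. Each had an exact permutation p of 0.0571 (two-sided, n = 3 and 4) and a Benjamini-Hochberg adjusted p of 0.109, so none passed the threshold. With the 2696 strongest peaks of each list, 4 chromosomes separated the groups, and another split of the rats separated 5. This comparison was added after the data were seen, and depth and input library differed between the groups in the same way.

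**Figure D3:**
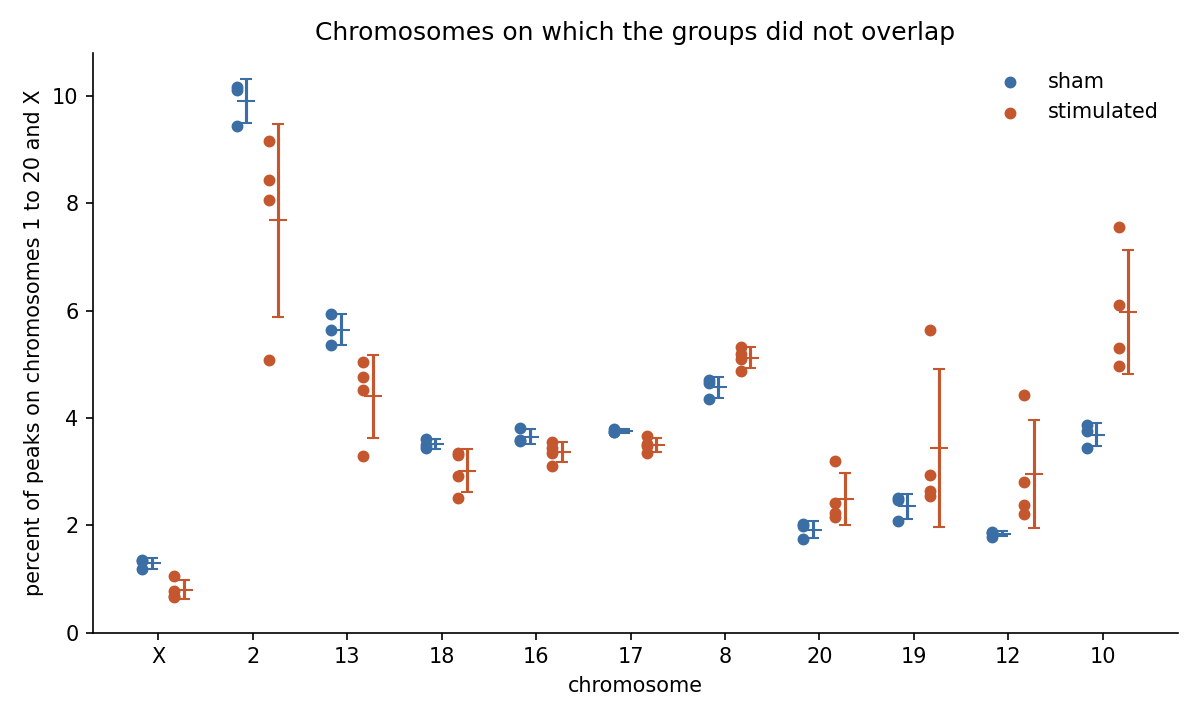
Share of each list's peaks, in percent of those on chromosomes 1 to 20 and X, for the 11 chromosomes on which the groups did not overlap; points are rats and bars give the mean and SD (n = 3 sham, n = 4 stimulated). Chromosome 10 lies at 3.44 to 3.87% in sham rats and 4.97 to 7.56% in stimulated rats.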

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

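All tests of explanations in this part were chosen after the result was seen. Among 32 measures examined in the 4 stimulated rats, 2 had 1 rat far from the other 3, and chance gives about 1 in 20. Mean peak width was 173 bp in stimulated rat 3, against 189 bp in the nearest other stimulated rat. Chromosome 19 held 5.64% of the peaks of stimulated rat 1, against 2.93% in the nearest other stimulated rat.

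The chromosome 19 value belongs to a list that shared few peaks with the others, and 3 technical explanations were weighed. Low depth is argued against, since stimulated rat 1 had 1.45 times the filtered tags of the next deepest library. Coordinates of another build are argued against, because 144 of the strongest 10% of its peaks met stimulated rat 4, 8.83 times the mean of 100 circular shifts (16.3 ± 3.38, SD). Weak calls alone do not account for it. Of its peaks with a −log10 q of at least 3, 10.4% met stimulated rat 4, against 37.5% to 42.5% for the sham lists. The share was 11.3% for stimulated rat 3, so a low share at this threshold was not particular to stimulated rat 1. In 1 Mb windows the peak counts of stimulated rat 1 had Spearman's rho of 0.62 with stimulated rat 4 and 0.11 at most with a sham list. With equal lists these values were 0.19 and 0.05. The 2786 windows are not independent replicates, and the stimulated lists shared 1 input. A poor precipitation or a mislabelled library may explain the list and stays untested, as does a difference of this animal after stimulation.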

How the results depend on the processing

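Alternatives were planned except peaks relative to filtered tags, distinct intervals, shifted chance, absolute differences, wide peaks left out, stimulated rats 1 and 3 left out, the chromosome count and the window correlations, all chosen after seeing the data. No test of peak number, covered length or overlap passed the threshold under any alternative, which the two-sided tests could not do with p as 2 times the smaller tail, nor the one-sided overlap test wherever rats were left out. With p from absolute differences (smallest possible 0.0286) peak number gave an exact p of 0.914 and covered length 0.886, and 0 of 21 chromosomes had an unadjusted p below 0.05 (smallest adjusted p 0.150). Their directions were not stable. With a −log10 q of at least 3 the log10 differences were −0.110 for peak number and −0.103 for covered length, and relative to filtered tags −0.449 for peak number. Leaving out 1 rat gave −0.174 to 0.360 for peak number, −0.175 to 0.372 for covered length and −0.61 to 1.32 (log2) for overlap within groups. Leaving out 1 rat also gave 6 to 50 stimulated-only regions, 48 to 733 sham-only regions and 13 to 85 regions in all rats, as fewer lists must then meet or lack a peak. Chromosomes separating the groups numbered 11 to 16 with 1 rat left out. The difference in window correlation within minus between groups kept its direction throughout. It was 0.12 at a −log10 q of at least 3, 0.20 to 0.30 with 1 rat left out and 0.19 without stimulated rats 1 and 3, no longer past the threshold, which the test could not pass with rats left out. Removing each chromosome's mean rank gave 0.26 (exact one-sided p = 0.0286). The stronger peaks of each list gave 2 stimulated-only regions and 8 in all rats. A −log10 q of at least 3 gave 2 stimulated-only, 24 sham-only and 5 all-rat regions, and 7 chromosomes. At least 4-fold enrichment gave 0 stimulated-only, 104 sham-only and 0 all-rat regions. Equal lists gave 1 stimulated-only and 8 all-rat regions, and 4 chromosomes. Without peaks wider than 1 kb, 7 regions were in all rats. Without stimulated rats 1 and 3 there were 18798 stimulated-only regions, 1313 in all rats and 19 chromosomes. The log10 differences were then 0.677 for peak number and 0.691 for covered length. For changes not following from fewer lists, the cause was not tested. For the 26 regions named by the fixed rule, the number of rats differed in 53 values under an alternative and did not in 77. All 10 sham-only regions changed with equal lists, and all 6 stimulated-only and all 10 all-rat regions at 4-fold enrichment. For the 10 regions chosen afterwards, 5 values differed and 45 did not. Those 10 were picked for high fold enrichment, so filters on peak strength could hardly remove them. No paired analysis was possible because the labels give every rat its own number, and the replicate numbers used here only name the rats of a group. Promoter share, CpG content, gene lists, genes with peaks in 1 group and promoter windows were not run, since no annotation of the build was used here. The effect of depth on the lists was not tested; filtered tags were 2436208 to 3668143 in sham and 4812579 to 17960510 in stimulated rats.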

Other observations

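Among the tests of this part, the equal-list and dense-window tests of gene density were set before their results were seen, whereas their counting intervals and all other tests were chosen after. The densest 1 Mb window was on chromosome 1 from 187000001 to 188000000 in every list except that of stimulated rat 1. It held 133, 146 and 133 peaks in sham rats 1 to 3, 150 in stimulated rat 2, 26 in stimulated rat 3 and 141 in stimulated rat 4, against 4 in stimulated rat 1. Stimulated rat 1 had its densest window on chromosome 1 from 56000001 to 57000000, with 58 peaks. That window also held 24, 17 and 13 peaks in sham rats 1 to 3, and 42, 1 and 49 in stimulated rats 2, 3 and 4. Some of the strongest shared peaks, chosen after their values were seen, included chromosome 2 at 134264702 to 134264988, enriched 19.4-, 33.6- and 24.6-fold in sham rats 1 to 3, and 9.68-, 7.50- and 13.9-fold in stimulated rats 2, 3 and 4. Chromosome 8 at 14105579 to 14105817 was enriched 13.5- and 13.3-fold in stimulated rats 2 and 4. It had no peak in a sham rat and none in stimulated rats 1 and 3.

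Peak density in the stimulated lists followed gene-rich chromosomes more than in the sham lists. Across 20 autosomes, which are not independent replicates, Spearman's rho with the protein-coding gene density of GRCr8 was −0.31, −0.34 and −0.13 in sham rats and 0.90, 0.41, 0.48 and 0.63 in stimulated rats. Without 139 windows dense in peaks, rho was −0.57, −0.68 and −0.52 in sham rats and 0.89, −0.07, 0.15 and 0.47 in stimulated rats, so that stimulated rat 2 no longer followed gene density. The lowest stimulated value was still 0.44 above the highest sham value (95% counting interval 0.10 to 0.54), which argues against a few windows as the whole cause of the difference between groups. With equal lists rho was −0.05, −0.26 and −0.35 in sham rats and 0.76, 0.18, 0.49 and 0.25 in stimulated rats. The gap was then 0.23, which met the rule set beforehand that every stimulated value lie above every sham value. Its 95% counting interval, added later, was −0.04 to 0.38, so the test does not decide on list length. Length itself did not divide the groups. Stimulated rats 1 to 4 had 9500, 109947, 2754 and 65074 peaks, and the sham rats 12269 to 32399. All 4 stimulated libraries were deeper than the deepest sham library and shared 1 input, so depth and input cannot be told apart from treatment. An effect of stimulation, which cannot be separated from that of diazepam, may contribute and stays untested.

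In every list the median pileup of peaks in the 13 regions of all rats was at least 10.0 times that of peaks in regions seen in 1 rat. High-copy or collapsed repeat sequence was first tested as tall pileup with lower fold enrichment in every list. That failed in 2 lists, sham rat 2 and stimulated rat 2, where the median fold was higher. The medians of pileup and fold included the mitochondrial peaks and were not computed without them. A second test, chosen after that failure and with related values already seen, recovered the local background from pileup and fold. The median of that background over peaks was at least 39.0 times the genome-wide background in every list. Without mitochondrial peaks it was at least 37.1 times. A local background above the genome-wide one comes from the input library, so input tags were also piled up at most of these peaks. Tall pileups at similar or lower fold force such a value, so it is no separate evidence, and the source of the input signal was not tested. A high copy number may underlie the tall pileups and stays open, and no biological explanation was tested.

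Other splits of the 7 rats bear on 3 counts. For stimulated-only regions, 9 of 35 splits gave at least the observed 6, the highest other being 1250, so chance is not excluded. For sham-only regions, 10 of 35 gave at least the observed 48, the highest other being 4131, so chance is not excluded. The highest counts came from splits that put stimulated rats 2 and 4 together with sham rats and thereby joined long lists. With equal lists, 11 of 35 splits gave at least the observed 1 stimulated-only region (highest other 64), and 2 of 35 at least the observed 56 sham-only regions (highest other 89). For chromosomes separating the groups, 1 of 35 splits, the real one, gave 11 and the highest other 9, but the count was chosen after this separation had been seen. With equal lists, 3 of 35 splits gave at least the observed 4 and the highest other gave 5, so chance is not excluded.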
